A study of Mus musculus with 52 samples.

How the data were processed

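The series holds 52 chromatin immunoprecipitation sequencing libraries of mouse cells, 43 from mouse embryonic stem cells (mESCs) and 9 from epiblast-like cells (EpiLCs). The libraries fall into 34 groups by cell type, antibody and genotype, of which 16 have 1 library and 18 have 2. Replicates are separate clones in most groups and separate libraries of the control line in others. Per the labels' protocols, fixation took 10 minutes in 1% formaldehyde. For Med1 they were first treated with 2 mM disuccinimidyl glutarate for 30 minutes. EpiLCs were harvested after 48 hours of differentiation. Per the series' design text, 100 µg of chromatin went into immunoprecipitations of histone marks, 200 µg into those of RNA polymerase II and 1 mg into those of Med1. Drosophila chromatin was added at 5% so that the authors could scale signal between libraries, besides their FPKM normalization. The submitters' processing notes name Trimmomatic 0.38, Bowtie2 2.3.4.1, bedtools 2.29.2 and the builds mm10 and dm6. Their role and settings are not given in the sources used here.

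The deposited tables analysed here are 3 region sets in mm10 coordinates, each with a chromosome, a start, an end and a strand. Per the series' design text, the mESC enhancers and the EpiLC enhancers came from earlier publications of other groups and were lifted over to mm10 by the authors. The EpiLC set was defined by H3K27ac, H3K4me1 and p300 peaks. The gene set is a non-redundant collection of UCSC genes from earlier work of the authors. The liftover tool and the rule that joined transcripts into gene intervals are not given in the sources used here. The tables have 0 columns with a value per library, so sequencing depth is unknown and signal per library was not analysed here. The planned comparisons of mutant with control libraries, with their limma tests and pseudocounts, therefore had no values to run on. What follows describes the regions over which the authors compared their libraries. These region sets are fixed lists with no replicates, so the p-values below compare a set with random positions or random gene lists and say nothing about variation between cultures.

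All coordinates are mm10 and are printed 1-based. In the gene table the start counts from 0, since start plus 1 and end together equal a RefSeq gene in 12038 rows, against 329 rows for the start itself. The counting of the enhancer tables could not be settled from their values. It was taken to be the same, which leaves their starts uncertain by 1 bp. Gene intervals were named by exact match to RefSeq (12038 rows), to GENCODE M21 genes (1406 rows) or to GENCODE M21 transcripts (1215 rows). Failing that, the annotated gene or transcript with a shared length of at least 0.8 of the joint length on the same strand was used (9152 rows). In total 23811 of 24402 rows received a name. Exact duplicates (120 rows) and rows that ended beyond their chromosome or lay on scaffolds (24 rows) were left out, which kept 24263 rows and 23745 symbols.

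Overlap between the enhancer sets was counted from 1 bp upwards and compared with 1000 seeded shuffles of the mESC enhancers within their chromosomes (bedtools 2.31.1). The position of each set against genes was compared with 1000 shuffles of the same kind. These p-values are one-sided permutation p-values, and the smallest they can give is 0.001. For the position against genes the side was that on which the observed value fell, without doubling. The annotation at an enhancer's centre was taken from GENCODE M21, with promoter meaning within 1 kb of any annotated transcription start site (TSS). For gene lists, each enhancer was tied to the TSS nearest its centre if that TSS lay within 50 kb of the enhancer. The TSS was the 5' end of the gene interval. The count of each list was compared with 10000 random lists of equal size matched on gene-length decile. This two-sided permutation test gives a smallest p of 0.0002, and p-values were adjusted by the Benjamini-Hochberg method over the 17 lists of each enhancer set. The difference between sets was tested with the same random lists, on the EpiLC share minus the mESC share.

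The 17 gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The lists cover naive pluripotency, general pluripotency, the formative and primed epiblast, homeodomain developmental regulators, mesoderm and endoderm regulators, neural regulators, trophoblast, the 2-cell stage, germ cells, Polycomb complexes, acetyltransferases with deacetylases and Mediator, canonical H3, H3.3 with its chaperones, ribosomal proteins, housekeeping genes, fibroblast and feeder markers, and muscle and liver genes as a silent control. The named genes are the 10 with most enhancers in each set, the 5 longest enhancers of each set and the 4 members of each list with most enhancers over both sets, with ties resolved by name. Members without an enhancer were counted and up to 4 of them named in list order. Some genes that this rule selects are not reported here.

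The overlap functions were checked against bedtools and gave the same 3773 and 823 regions for the overlap of 1 bp and the reciprocal overlap. The list test was tested on simulated data, with 20 simulated sets over 23745 genes and 1000 random lists each. A naive pluripotency list raised 3-fold was called in 65% of simulated mESC sets and 70% of simulated EpiLC sets. For the ribosomal protein list these shares were 45% and 80%. Unchanged lists were called in 0% of cases in both. The motif counts of the closing section used 13 consensus sequences on both strands, each read backwards as its control, with 95% bootstrap intervals from 1000 resamples of the regions. Alternatives covered the overlap rule, the shuffle, the distance to the TSS, the matching of random lists, the gene annotation and subsets of enhancers. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.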

Results

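The study mapped histone marks and transcription machinery in pluripotent mouse cells whose histone H3 carries arginine in place of lysine 27, the residue that is methylated by Polycomb repressive complex 2 and acetylated at active enhancers. Naive mESCs, grown without feeders in LIF and inhibitors of GSK3 and MEK1, were compared with EpiLCs, which resemble the early post-implantation epiblast. Control cells (ABE) were compared with clones mutated in canonical H3 alone (cK27R) or in all H3 (pK27R). Further libraries came from SUZ12 knockout cells, which lack a core Polycomb subunit. The H3.3 libraries came from control cells, an H3.3 knockout, and knockout clones with add-back of wild-type (pK27WT) or K27R histone, the latter under the name pK27R. Antibodies against H3K27me2 gave 5 libraries, H3K27me3 7, H3K27ac 11 with a rabbit and 5 with a mouse antibody, RNA polymerase II 9, the Mediator subunit Med1 5 and H3.3 6. The remaining 4 libraries were inputs. The tables analysed here hold the regions over which these libraries were compared, namely 8794 mESC enhancers, 16576 EpiLC enhancers and 24402 gene intervals. Signal per library, and with it each comparison of mutant with control cells, was not analysed here. The results below describe where these enhancers lie and which genes they surround. The mESC and EpiLC enhancers were defined in separate earlier publications, so differences between the sets in number, width, position, gene lists or sequence cannot be told apart from differences in how each set was defined.

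The EpiLC enhancers were more numerous and wider than the mESC enhancers. Median length was 711 bp for mESC enhancers (quartiles 572 and 919 bp) and 1750 bp for EpiLC enhancers (quartiles 1085 and 2900 bp). The mESC enhancers covered 15.7 Mb, or 0.574% of the chromosomes, and the EpiLC enhancers 39.4 Mb, or 1.45%. Enhancers longer than 10 kb made up 4.58% of the mESC set (403 regions) and 1.38% of the EpiLC set (228 regions). Chromosome 11 had the highest density in both sets, with 4.60 mESC and 9.80 EpiLC enhancers per Mb. The X chromosome carried 1.43 and 1.99 per Mb, below every autosome in both sets. The Y chromosome held 0 mESC and 8 EpiLC enhancers.

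The longest mESC enhancers included one beside Prdm14, and the longest EpiLC enhancers one at Etv5. In the mESC set the longest spanned 50163 bp on chromosome 15 (25724348 to 25774510), centred in an intron of Myo10, with no TSS of the gene table within 50 kb. The next, 45150 bp on chromosome 1 (13059535 to 13104684), was intergenic and 22.5 kb from the TSS of Prdm14, a regulator of naive pluripotency and germ cell formation. A region of 41890 bp on chromosome 5 (119679584 to 119721473) covered the TSS of Tbx3os2, a noncoding transcript beside Tbx3. A region of 35621 bp on chromosome 14 (122255317 to 122290937) was centred in an intron of Clybl, and one of 33018 bp on chromosome 1 (77440263 to 77473280) in an intron of Epha4. Each of these 5 overlapped at least 1 EpiLC enhancer. In the EpiLC set the longest spanned 38025 bp on chromosome 11 (69679302 to 69717326) and covered the TSS of Tnfsf12. The next, 33904 bp on chromosome 16 (22385202 to 22419105), was centred within 1 kb of an annotated TSS inside Etv5, an ETS factor of the exit from naive pluripotency. A region of 33375 bp on chromosome 15 (102385627 to 102419001) covered the TSS of Sp1 and was the only one of the 5 without an mESC enhancer in it. The others were centred in introns. One of 32875 bp on chromosome 1 (136669177 to 136702051) was centred in Gm19705 and covered its TSS, and one of 31625 bp on chromosome 2 (20647052 to 20678676) was centred in Etl4.

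To ask how many regions the sets have in common, they were overlapped. Of the 8794 mESC enhancers, 3773 (42.9%) overlapped an EpiLC enhancer, against a mean of 228.8 ± 15.01 (SD) over 1000 shuffles, a ratio of 16.5 (one-sided permutation p = 0.001, the smallest possible). That left 5021 mESC-only enhancers and 12290 EpiLC-only enhancers, while 4286 EpiLC enhancers (25.9%) overlapped an mESC enhancer. Overlap rose with the length of the mESC enhancer, from 21.6% in the shortest quartile (median 490 bp) to 70.6% in the longest (median 2672 bp). The count depended on the overlap rule. It was 823 where at least 50% of both regions had to be shared and 2296 for regions of equal width of 500 bp, with ratios to the shuffles of 43.6 and 40.1.

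The EpiLC set contained far more promoter regions than the mESC set. Centres within 1 kb of a GENCODE TSS made up 25.7% of EpiLC enhancers (4261 regions) and 8.92% of mESC enhancers (784 regions), against shuffled means of 6.18% ± 0.187 and 6.09% ± 0.258 (SD of 1000 shuffles). The share was 29.7% in EpiLC-only enhancers and 14.4% in EpiLC enhancers that overlapped the mESC set. Introns held 45.5% of mESC centres, above the shuffled 39.0%, and 34.5% of EpiLC centres, below the shuffled 39.2%. Intergenic positions held 42.4% and 36.9%, below the shuffled 51.6% and 51.3%. Coding exons held 0.534% and 0.658%, below the shuffled 0.977% and 0.999%. Each of these 8 differences from the shuffles had a one-sided permutation p of 0.001, the smallest possible, on the side where the observed value fell. Median distance to the nearest TSS of the gene table was 32.3 kb for mESC and 19.6 kb for EpiLC enhancers, against 62.7 kb and 61.2 kb after shuffling.

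**Figure D1:**
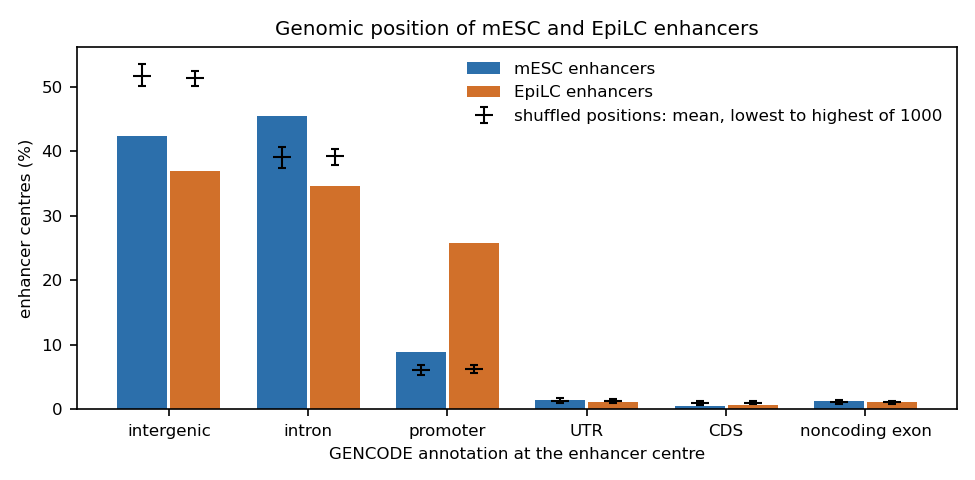
Share of enhancer centres (%, vertical axis) by GENCODE annotation for the 8794 mESC and 16576 EpiLC enhancers. Black marks give the mean of 1000 shuffles, with bars from the lowest to the highest shuffle. Promoter positions held 25.7% of EpiLC and 8.92% of mESC centres.

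In the authors' gene table, 62.0% of mESC enhancers and 65.9% of EpiLC enhancers overlapped a gene interval, against shuffled means of 56.3% and 56.9%. These shares are raised by a few very long intervals. The table has 97 intervals, exact duplicates included, longer than the longest RefSeq gene (3171119 bp), up to 149155143 bp, of which 65 passed the filters. An interval of 102 Mb on chromosome 4 (48045335 to 150248873) ends where Eno1, encoding a glycolytic enzyme, ends. Without such intervals the shares were 48.9% for mESC and 54.2% for EpiLC enhancers, against shuffled means of 40.6% and 41.4%. This filter was chosen after seeing the data.

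Genes of pluripotency and of Polycomb complexes, together with neural regulators, were surrounded by more mESC enhancers than random genes of like length. The 25 naive pluripotency genes had 36 mESC enhancers against 6.12 in random lists (95% range 2 to 12), a ratio of 5.88. The 15 general pluripotency genes had 17 against 3.02 (range 0 to 7), the 23 formative and primed epiblast genes 19 against 5.05 (range 1 to 10), the 21 Polycomb genes 19 against 5.14 (range 1 to 10) and the 25 neural regulators 18 against 4.46 (range 1 to 9). These 5 of 17 lists had an adjusted p of 0.00068 by permutation, the smallest reached with these random lists. All 5 passed in every alternative, but some ratios moved by over 1.5 times. When every gene within 50 kb was counted, the ratio fell to 3.70 for naive genes, from 5.63 to 3.31 for general pluripotency genes (adjusted p = 0.00085 each, highest alternatives 0.00085 and 0.00136) and from 4.03 to 2.20 for neural regulators (adjusted p = 0.00544). The neural ratio was 2.29 with random lists matched on distance to neighbouring TSSs (adjusted p = 0.015, highest alternative 0.0204), and the formative and primed ratio went from 3.76 to 2.47 without the first 231 rows of the mESC table (adjusted p = 0.0333, the highest of its alternatives). The other 12 lists had adjusted p-values of 0.515 or more. Among these, 45 homeodomain regulators had 8 mESC enhancers against 7.99, 25 mesoderm and endoderm regulators 6 against 5.47, and 20 acetyltransferase, deacetylase and Mediator genes 10 against 6.06. Trophoblast genes had 4 against 2.58, germ cell genes 4 against 3.77, 2-cell-stage genes 0 against 1.96, canonical H3 genes 1 against 0.913 and H3.3 genes with chaperones 1 against 2.70. Ribosomal protein genes had 4 against 5.48, housekeeping genes 1 against 3.70, fibroblast and feeder markers 3 against 3.25, and muscle and liver genes 2 against 3.80. When every gene within 50 kb was counted, which lets 1 enhancer count for several neighbouring genes, canonical H3 genes exceeded random lists (ratio 3.27, adjusted p = 0.00963, range over its alternatives up to 1) and 2-cell-stage genes fell below them (ratio 0, adjusted p = 0.0219, range up to 0.899).

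Counts at single genes are of regions, and 1 long mESC region can overlap several EpiLC regions. A higher EpiLC count at a gene therefore need not mean further sites. Among naive genes, 23 of 25 had at least 1 mESC enhancer. Klf2, a naive pluripotency factor on chromosome 8 (72319062 to 72321654), had 2 mESC and 5 EpiLC enhancers. Il6st, the LIF co-receptor on chromosome 13 (112464070 to 112506860), had 3 and 3. Prdm14 on chromosome 1 (13113428 to 13127163) had 2 and 4, and Dppa4 on chromosome 16 (48283735 to 48294292) had 1 and 4. Esrrb and Stat3 had none in either set under this rule. Esrrb, a naive factor on chromosome 12 (86361117 to 86521628), nevertheless held 2 mESC and 6 EpiLC enhancers inside its interval, the nearest 104.6 kb from the 5' end that the table gives. That count was made after its values were seen. Of the general pluripotency genes, Sall4 on chromosome 2 (168748332 to 168767201) had 1 mESC and 7 EpiLC enhancers, 5 of these 7 overlapping an mESC enhancer. Sox2 on chromosome 3 (34649995 to 34652460) had 2 and 6, 3 of these 6 overlapping an mESC enhancer. Foxd3 on chromosome 4 (99656299 to 99658671) had 2 and 3, and Tcf3 on chromosome 10 (80409165 to 80433653) alone had none. That interval is the E2A gene, and Tcf7l1, whose product was formerly called TCF3, was not in the list.

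In the EpiLC set, 6 of 17 lists exceeded random lists. The formative and primed epiblast genes had 55 EpiLC enhancers against 11.2 (95% range 4 to 21), a ratio of 4.92. Naive genes had 47 against 12.98 (range 5 to 23), general pluripotency genes 35 against 6.97 (range 2 to 15) and Polycomb genes 34 against 11.1 (range 4 to 20), each with an adjusted p of 0.00085 by permutation. When every gene within 50 kb was counted, the ratio fell to 2.99 for formative and primed genes, from 3.62 to 1.96 for naive genes and from 5.02 to 2.80 for general pluripotency genes, which still passed (highest adjusted p over their alternatives 0.00146). Housekeeping genes had 26 against 9.03 (range 3 to 17, adjusted p = 0.00272 by permutation) and ribosomal protein genes 31 against 13.4 (range 6 to 23, adjusted p = 0.0085 by permutation). Of the 31 ribosomal regions 23 (74.2%) were centred within 1 kb of a TSS, as were 14 of the 26 housekeeping regions (53.8%). Neither list passed without promoter-centred regions, a setting chosen after seeing the data, where the ratio was 0.975 for ribosomal genes (adjusted p = 1 by permutation, range over its alternatives 0.000567 to 1) and 2.18 for housekeeping genes (adjusted p = 0.208, range 0.000567 to 0.208). The ribosomal call was also lost with random lists not matched on length (adjusted p = 0.0759).

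The remaining 11 lists did not pass in the EpiLC set. Muscle and liver genes, the silent control, had 2 EpiLC enhancers against 9.26 (adjusted p = 0.067 by permutation). Homeodomain regulators, the classical Polycomb targets, had 10 against 18.9, a ratio of 0.53 (adjusted p = 0.187). That list fell below random lists when enhancers were tied only within 20 kb (ratio 0.277, adjusted p = 0.0102) or to every gene within 50 kb (ratio 0.38, adjusted p = 0.000567), and the adjusted p reached 0.809 without promoter-centred regions. Canonical H3 genes had 6 against 2.03, with 5 of these 6 regions at a promoter (adjusted p = 0.187). Neural regulators had 16 against 10.5, trophoblast genes 10 against 6.22, germ cell genes 11 against 8.01, and acetyltransferase, deacetylase and Mediator genes 13 against 12.04. Fibroblast and feeder markers had 8 against 7.11, mesoderm and endoderm regulators 10 against 11.99, 2-cell-stage genes 2 against 4.81 and H3.3 genes with chaperones 3 against 5.52. When every gene within 50 kb was counted, so that 1 enhancer could count for several neighbouring genes, canonical H3 genes passed above random lists (ratio 4.47, adjusted p = 0.000567, range over its alternatives up to 1). In that setting the silent control (ratio 0.331, adjusted p = 0.00378, range up to 0.52) and 2-cell-stage genes (ratio 0.233, adjusted p = 0.0126, range up to 0.825) fell below them. Canonical H3 genes also passed with random lists matched on distance to neighbouring TSSs (ratio 3.45, adjusted p = 0.0398), the silent control fell within 100 kb (ratio 0.191, adjusted p = 0.0379), and neural regulators passed with GENCODE TSSs, a setting chosen after seeing the data (ratio 2.32, adjusted p = 0.0277, range up to 1).

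**Figure D2:**
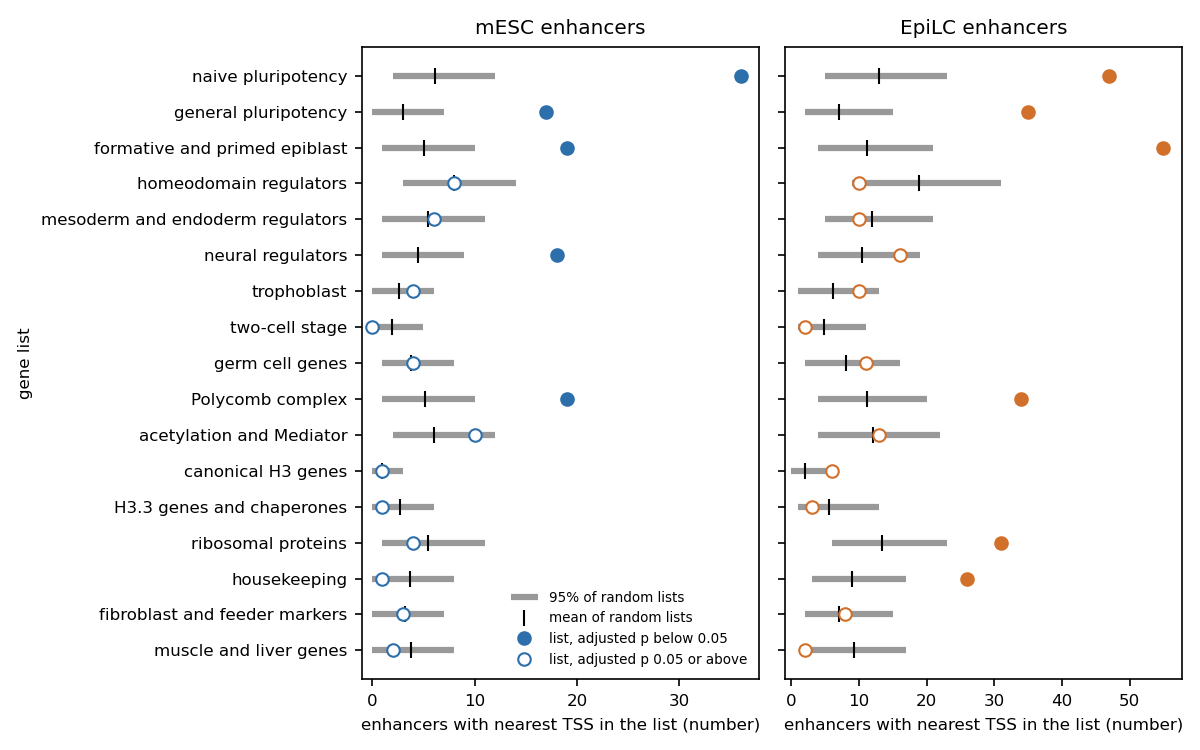
Number of enhancers whose nearest TSS within 50 kb belongs to each of the 17 gene lists (horizontal axis), for mESC enhancers (left) and EpiLC enhancers (right). Grey bars span 95% of 10000 random lists, black ticks their mean, and filled points have an adjusted p below 0.05. Naive pluripotency genes stand at 36 mESC enhancers against a mean of 6.12, and formative and primed epiblast genes at 55 EpiLC enhancers against 11.2.

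The lists were then compared between the sets, to ask whether naive and primed genes differ in their share of each set. Naive genes took 0.409% of mESC and 0.284% of EpiLC enhancers, a difference beyond random lists of -0.135 percentage points (adjusted p = 0.00085 by permutation). Formative and primed genes took 0.216% and 0.332%, a difference of 0.106 points beyond random lists (adjusted p = 0.00136). Neural regulators took 0.205% and 0.0965%, a difference of -0.12 points (adjusted p = 0.00085). Ribosomal protein genes (0.0455% and 0.187%) and housekeeping genes (0.0114% and 0.157%) took larger EpiLC shares, both with an adjusted p of 0.00085. The other 12 lists had adjusted p-values of 0.15 or more. Naive genes had 36 mESC and 47 EpiLC enhancers, against means of 6.12 and 12.98 in their random lists. Neural regulators had 18 and 16, against means of 4.46 and 10.5. Shares resting on fewer enhancers vary less, so the spread of random lists is too narrow for lists enriched in either or both sets. Each list called here was enriched in either or both sets, so these p-values do not by themselves show that the sets differ. The naive difference was lost without the first 231 rows of the mESC table (-0.018 points, adjusted p = 0.781) and without promoter-centred regions (-0.0763 points, adjusted p = 0.0646), with a lowest alternative p of 0.00068. The primed difference was lost within 20 kb (0.0208 points, adjusted p = 0.436; lowest 0.00085), and the ribosomal difference without promoter-centred regions (0.00726 points, adjusted p = 0.869; lowest 0.00068). Some differences stayed called but moved by over 1.5 times. The primed difference was 0.181 points without the first 231 mESC rows, the neural one -0.0749 within 20 kb and -0.202 when every gene within 50 kb was counted, the ribosomal one 0.277 in the latter setting, and the housekeeping one went from 0.133 to 0.0802 without promoter-centred regions. Differences also appeared that the main setting did not call. Homeodomain regulators took a smaller EpiLC share when every gene within 50 kb was counted (-0.301 points, adjusted p = 0.00068) or with GENCODE TSSs (-0.092 points, adjusted p = 0.0181; highest alternative 0.869). Larger EpiLC shares were called for canonical H3 genes when every gene within 50 kb was counted (0.132 points, adjusted p = 0.00068; highest 0.869) and for general pluripotency genes without the first 231 mESC rows (0.0628 points, adjusted p = 0.0258; highest 0.939).

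Every mESC enhancer of the formative and primed genes overlapped an EpiLC enhancer. Of these 19 regions, 0 were mESC-only, against 57.1% of all mESC enhancers. Of the 55 EpiLC enhancers of the list 29 were EpiLC-only, a smaller share than the 74.1% of all EpiLC enhancers. Pou3f1, encoding the formative factor OCT6, on chromosome 4 (124657646 to 124660655) had 0 mESC and 7 EpiLC enhancers. Spry4 on chromosome 18 (38586265 to 38601268) had 3 and 6, 5 of these 6 overlapping an mESC enhancer. Spry2 on chromosome 14 (105891947 to 105896819) had 3 and 5, all 5 overlapping an mESC enhancer, and Dusp6 on chromosome 10 (99263231 to 99267489) had 1 and 5, 4 of them EpiLC-only. The products of these 3 genes restrain FGF and ERK signalling. Zic2, Tead2, Cdh2 and Car14 had none. Naive genes had 11 mESC-only enhancers beside 25 that overlapped an EpiLC enhancer, a smaller mESC-only share than in the whole set. Neural regulators had 11 mESC-only enhancers of 18, a share close to that of the whole mESC set. They included 2 at Lmx1b on chromosome 2 (33564536 to 33640511) and 2 of the 3 at Otx1 on chromosome 11 (21994764 to 22001651). Sox1 had 1 mESC and 3 EpiLC enhancers and Nes, encoding nestin, 1 and 2. There were none at 8 neural regulators, including Pax6, Lmx1a, Irx3 and Irx5.

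Among the Polycomb genes, Jarid2, encoding an accessory subunit of Polycomb repressive complex 2, on chromosome 13 (44730774 to 44921643) had 3 mESC and 8 EpiLC enhancers, 7 of these 8 overlapping an mESC enhancer. Aebp2 on chromosome 6 (140622663 to 140678472) had 2 and 5, Phc1 on chromosome 6 (122317731 to 122340227) had 2 and 4, and Rbbp7 on the X chromosome (162760372 to 162779090) had 1 and 4. None of the mESC enhancers at these 4 genes was mESC-only. The list had 5 mESC-only enhancers of 19, a smaller share than the 57.1% of all mESC enhancers. They were 3 at Mtf2 on chromosome 5 (108065674 to 108109219) and 2 at Eed on chromosome 7 (89954654 to 89980976), genes without an EpiLC enhancer that were named after their values were seen. There were 7 Polycomb genes without an enhancer, among them Ring1, Pcgf1, Pcgf2 and Pcgf6. Kat6b, an acetyltransferase gene, had 2 mESC and 4 EpiLC enhancers, Kat2b 1 and 2, and the deacetylase genes Hdac1 and Hdac2 1 and 1 each. Ep300 and Crebbp, whose products acetylate H3K27, had none, nor had Kat2a and Kat5. Of the H3.3 genes and chaperones, Asf1a, H3f3a and Hira had 1 EpiLC enhancer each and Atrx 1 mESC enhancer. H3f3b and Daxx were among the 6 without any. Of the canonical H3 genes, H3c3 had 1 in each set, and H3c1, H3c11 and H3c13 had 1 EpiLC enhancer each.

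Homeodomain regulators and mesoderm and endoderm regulators passed the test in neither set. Most of the homeodomain list were genes of the Hox clusters, so its result bears mainly on those clusters. Other homeodomain genes, such as Otx1, Lmx1b and En1, stood in the neural list instead. Of 45 homeodomain regulators 33 had no enhancer, including Hoxa2, Hoxa3 and Hoxa5. Hoxb1 and Hoxc13 each had 1 mESC-only and 2 EpiLC-only enhancers, and Nkx6-1 and Pax3 1 in each set. Of 25 mesoderm and endoderm regulators 18 had none, including Mesp1, Mixl1, Sox17 and Gata4. Brachyury (T), on chromosome 17 (8434423 to 8442496), had 2 in each set, all shared. Eomes, on chromosome 9 (118478189 to 118486132) and also in the trophoblast list, had 0 mESC and 3 EpiLC enhancers. Foxa2 had 1 and 2, and Gsc 2 and 1. Of the trophoblast genes, Tfap2c had 3 in each set, and Krt8 had 2 and Ascl2 1 in the EpiLC set only. Among germ cell genes, Prdm1, encoding BLIMP1, on chromosome 10 (44437174 to 44458748) had 4 mESC and 7 EpiLC enhancers, and Nanos3, Slc25a31 and Stk31 1 EpiLC enhancer each. Gm5039 and Zscan4d were the 2-cell-stage genes with an enhancer, 1 each in the EpiLC set.

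For the control lists, Rps19 had 1 mESC and 2 EpiLC enhancers, Rpl11 1 and 1, and Rpl19 and Rpl35 0 and 2. Eef1a1 had 0 and 4, Eno1 1 and 2, Ywhaz 0 and 3 and Gapdh 0 and 2. Of the fibroblast and feeder markers, Fbln1 had 0 and 3, Fn1 1 and 2, and Col3a1 and Twist2 1 and 1. Of the muscle and liver genes, Cyp3a11 had 1 and 1, Fga 1 and 0, and Mb 0 and 1, while 17 of 20 had none, including Alb, Apoa1, Apob and Ttr.

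Over all 23745 named genes, 4533 had at least 1 mESC enhancer, 7475 at least 1 EpiLC enhancer and 2915 both, while 14652 (61.7%) had none. The most mESC enhancers at a gene were 4, at Prdm1 and at Akap12, a protein kinase A scaffold on chromosome 10 (4266329 to 4359471). A further 89 genes had 3, the first 8 by name being 0610039H22Rik, 9630028H03Rik, A230009B12Rik, Abhd2, Actn1, Adam19, Arid1b and Auh. The most EpiLC enhancers were 9, at Pim1, a kinase gene on chromosome 17 (29491045 to 29495459) with 3 mESC enhancers, of which 0 were mESC-only. Next came 7 genes with 8 each, namely 1700108J01Rik, Aff1, Ddit4, Gm38509, Jarid2, Mrps23 and Tle3. They included Tle3, a Groucho corepressor on chromosome 9 (61372366 to 61418497), and Ddit4, an mTOR inhibitor on chromosome 10 (59949675 to 59951770). Of the 18 genes with 7 EpiLC enhancers, 1700121N20Rik and Atf7ip came first by name.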

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

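The settings named here as added were chosen after seeing the data, namely shuffles outside assembly gaps, gene intervals no longer than the longest RefSeq gene, GENCODE protein-coding TSSs, the mESC set without its first 231 rows and the sets without promoter-centred enhancers. No paired analysis was possible because the tables analysed here carry no values per library, although clones of different genotypes share numbers in the labels. For the same reason the alternatives of pseudocount, filter on low values, centring, trend, samples in the fit, leave-one-out, ABE replicate 2 alone, count tests, replicate block, and camera or fry settings were not run. The overlap of the enhancer sets stayed above shuffles under every rule tried, with 823 regions for the reciprocal rule (ratio 43.6) and 2296 at equal width (ratio 40.1), both stricter by construction; with merged regions, within 1 kb and with either other shuffle it stayed within 1.5 times. Without the overlong gene intervals the share overlapping a gene was 48.9% for mESC and 54.2% for EpiLC enhancers. Measured to whole gene intervals instead of the TSS, the median distance was 0 kb in both sets, since most enhancers overlap an interval. Lists below random lists, 0 in both sets, became 1 of mESC and 3 of EpiLC when every gene within 50 kb was counted, and 1 of EpiLC within 20 kb and within 100 kb; the cause was not tested. Lists with a larger mESC share, 2 in all, became 1 without the first 231 rows and 1 without promoter-centred enhancers. The ribosomal protein ratio in EpiLC fell from 2.31 to 0.975, close to random lists, without promoter-centred enhancers, since 74.2% of its regions were left out. Of the values for single lists, 370 kept their side of the threshold, 14 passed it anew and 6 no longer passed. The ribosomal protein ratio in EpiLC was 1 more that no longer passed, with a value just below 1. Sequencing depth is unknown, so no limit from depth can be given.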

Other observations

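The tests on the overlong gene intervals, and the tests of GC content for the OTX motif and for ESRRB matches per kb, were chosen only after the result was seen. The enhancer classes differed in sequence, which cannot be told apart from how each set was defined. In particular, if binding of a factor entered the selection of the mESC regions, its motif would be raised there by that selection. Matches to an octamer (OCT) consensus stood at 0.162 per kb in mESC-only enhancers (95% bootstrap interval 0.151 to 0.175), 0.112 in mESC enhancers that overlapped an EpiLC enhancer and 0.071 in EpiLC-only enhancers (0.0674 to 0.0748), against 0.088 at shuffled positions. The last order turned among regions of 45% to 55% GC, with 0.0633 in EpiLC-only enhancers (0.0592 to 0.0676) against 0.0422 at shuffled positions (0.0388 to 0.0459) and 0.137 in mESC-only enhancers (0.120 to 0.154). The joint OCT-SOX consensus, bound by OCT4 with SOX2, had 54 matches in mESC-only enhancers (0.0101 per kb, 0.00746 to 0.0131) and 37 in EpiLC-only enhancers (0.00146 per kb, 0.00103 to 0.00192), against 0.00133 per kb at shuffled positions. ESRRB matches stood at 0.0593 per kb in mESC-only and 0.0325 in EpiLC-only enhancers. For KLF the values were 0.183 (0.170 to 0.197) and 0.177 (0.172 to 0.183), and in the GC band 0.249 (0.226 to 0.273) and 0.203 (0.195 to 0.211). TFCP2L1 matches were not higher in mESC-only enhancers, at 0.0284 (0.0238 to 0.0332) against 0.0312 (0.0284 to 0.0339), and in the band at 0.0355 (0.0279 to 0.0437) against 0.0355 (0.0318 to 0.0398). OTX matches were not separable over all regions, at 0.447 (0.438 to 0.457) in EpiLC-only and 0.435 (0.416 to 0.455) in mESC-only enhancers, against 0.431 (0.426 to 0.437) at shuffled positions, and were higher in EpiLC-only enhancers in the band, at 0.476 (0.464 to 0.488) against 0.408 (0.379 to 0.436). GRHL matches were higher in EpiLC-only enhancers, at 0.103 (0.0987 to 0.108) against 0.0837 (0.0749 to 0.0918), with overlapping intervals in the band, at 0.0967 (0.0913 to 0.102) against 0.0803 (0.0688 to 0.0932). ZIC matches were higher in EpiLC-only enhancers, at 0.408 (0.394 to 0.425) against 0.334 (0.318 to 0.350), but not separable in the band, at 0.445 (0.424 to 0.472) against 0.441 (0.414 to 0.466). TEAD matches were lower in EpiLC-only enhancers, at 0.591 (0.580 to 0.603) against 0.678 (0.644 to 0.722), and in the band at 0.603 (0.588 to 0.619) against 0.664 (0.627 to 0.707). SOX matches stood at 0.266 (0.252 to 0.283) in mESC-only and 0.144 (0.139 to 0.149) in EpiLC-only enhancers, and TCF/LEF matches at 0.552 (0.529 to 0.572) and 0.379 (0.371 to 0.386). CTCF went the other way, at 0.0142 (0.0111 to 0.0174) and 0.0223 (0.0204 to 0.0242). These intervals stayed apart in the band, whereas FOX was not separable, at 0.175 (0.163 to 0.187) and 0.163 (0.158 to 0.168). In the band SOX and TCF/LEF stood at 0.134 and 0.371 in EpiLC-only enhancers, near the shuffled 0.137 and 0.370. CTCF in EpiLC-only enhancers exceeded the shuffled 0.0129 (0.0120 to 0.0139) over all regions. In the band it was not separable, at 0.0285 (0.0257 to 0.0313) against the shuffled 0.0238 (0.0211 to 0.0262). Mean GC content was 44.4% in mESC-only, 46.3% in shared and 49.1% in EpiLC-only enhancers and 41.97% at shuffled positions, and CpG dinucleotides numbered 10.6, 12.3, 21.03 and 8.57 per kb.

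The order of rows in the EpiLC table followed promoters. In the first decile of rows 78.5% of regions were centred within 1 kb of a TSS and 11.9% overlapped an mESC enhancer, whereas in the last decile these shares were 9.78% and 30.9%. Median length went from 2425 to 1050 bp.

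Motifs were also counted relative to the same sequence read backwards, a control that does not remove all composition, since at shuffled positions the ratio was 1.34 for ESRRB, 1.06 for OTX and 5.99 for TFCP2L1. Wider EpiLC regions might dilute every motif towards its background. Of the 4 epiblast motifs named in advance, however, OTX moved away from its background in this ratio. GRHL did too, but its ratio cannot decide the question. The GRHL consensus can hold a CpG dinucleotide and its reversed sequence cannot, so the ratio can rise with CpG content. CpG dinucleotides numbered 21.03 per kb in EpiLC-only regions, 10.6 in mESC-only regions and 8.57 at shuffled positions. For OTX over all regions, matches per kb were not separable between the classes, so its ratio there also reflects the reversed control. In the GC band OTX matches per kb were 0.476 (0.464 to 0.488) in EpiLC-only regions. They were 0.408 (0.379 to 0.436) in mESC-only regions and 0.410 (0.398 to 0.422) at shuffled positions. The OTX ratio was 1.40 (1.36 to 1.45) in EpiLC-only and 1.03 (0.973 to 1.10) in mESC-only regions, and the GRHL ratio 0.958 (0.903 to 1.02) and 0.675 (0.590 to 0.773), against 0.590 (0.566 to 0.614) at shuffled positions. Dilution stays open for ESRRB and for TEAD, with TEAD ratios of 1.70 (1.65 to 1.75) and 1.92 (1.80 to 2.07) against 1.74 (1.71 to 1.78). The ZIC ratios were 14.8 (13.6 to 16.2) and 21.8 (17.9 to 28.0), but ZIC matches per kb over all regions argue against dilution. They were 0.408 (0.394 to 0.425) in EpiLC-only and 0.334 (0.318 to 0.350) in mESC-only regions, against 0.220 (0.215 to 0.224) at shuffled positions. In the GC band the 2 classes were not separable in ZIC matches per kb, so there dilution stays open. For ZIC the shuffled ratio of 18.1 (16.8 to 19.7) lay above that of EpiLC-only regions, which dilution alone would not give. At equal GC, however, their intervals overlapped, 16.6 (14.9 to 18.8) and 14.9 (13.4 to 16.8). The reversed ZIC sequence holds a CpG dinucleotide, so differences in CpG content can also move the ZIC ratios. GC content does not account for the difference in OTX ratio, since between 45% and 55% GC the ratios were 1.56 (1.5 to 1.62) and 1.12 (1.02 to 1.23). For ESRRB, matches per kb in that band argue against GC content, with 0.0601 (0.0491 to 0.0709) in mESC-only and 0.0377 (0.0347 to 0.0410) in EpiLC-only regions, while for the ratio it stays open, since 3.42 (2.43 to 5.10) and 2.67 (2.27 to 3.18) have overlapping intervals. The hypothesis that motifs of naive factors are more frequent in mESC-only enhancers asked for higher ratios of ESRRB, KLF and TFCP2L1 together. That joint prediction was not met, because the TFCP2L1 intervals overlapped, although the overlap does not show equal ratios. The ESRRB ratio was higher over all regions, 4.12 (3.18 to 5.39) against 2.51 (2.21 to 2.86), but not separable in the GC band. For TFCP2L1 the ratios were not separable, 6.33 (4.36 to 10.5) against 6.29 (5.20 to 7.74). KLF was mixed, with a higher ratio over all regions, 2.02 (1.84 to 2.23) against 1.70 (1.63 to 1.78), but overlapping intervals in the GC band, 1.91 (1.70 to 2.16) against 1.76 (1.67 to 1.86).

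The mESC table opens with a sorted block of 231 rows, with a median length of 8667 bp against 703 bp in the 8563 rows after it. Of the block, 223 regions (96.5%) overlapped an EpiLC enhancer, against 41.5% of later rows. In the block 16 regions were tied to a naive or general pluripotency gene, among them Pou5f1, Nanog, Sox2, Klf2, Prdm14 and Tfcp2l1, named after their values were seen. Length alone was argued against, since 10000 draws of later rows matched on length gave a mean of 1.29 such regions and at most 7, so that the block held 12.4 times the mean (one-sided permutation p = 0.0001, the smallest possible). The block may be the super-enhancers of the source publication, a hypothesis that the table itself does not label.

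The overlong gene intervals may arise where copies of a gene at different loci were joined into 1 interval. Of the 97, 71 (73.2%) had a start or end exactly on an annotated gene boundary, against 2.06% after moving the positions by 1 kb, which argues against coordinates of another build. Among the 28 with both ends on such boundaries, exact duplicates included, 27 shared no gene between start and end and 18 no chromosome. Boundaries were matched by position on any sequence of the assembly, so starts at position 1 also matched genes of scaffolds or of the mitochondrial genome. An interval listed on both chromosome 12 and chromosome X (88759474 to 109544620) starts where Mir1906-2 starts on the X chromosome and ends where Mir1906-1 ends on chromosome 12. No biological explanation was tested for this pattern.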
